A study of seawater metagenome with 7 samples.

How the data were processed

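Total RNA from plankton filtered from whole seawater at 2 stations in the western tropical North Atlantic was measured on 7 one-colour (Cy3) Agilent arrays, 4 from station 2 (4, 11, 21 and 30 m) and 3 from station 19 (2, 21 and 36 m). Each depth has 1 array, so the arrays of a station are its depth profile and the spread within a station includes any change with depth. Nothing in the labels says how many separate collections stand behind an array, so p-values measure the spread between these arrays only. The labels name the symbiotic cyanobacteria Richelia intracellularis and Calothrix rhizosoleniae and 4 genomes.

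Per the file headers, the deposited processed signal of each spot is a fluorescence intensity that Agilent Feature Extraction (version 10.7.3.1 per the submitters' processing notes) background-subtracted and detrended within the array. The deposited median signal and local background median are raw pixel intensity values per the file headers, and the deposited outlier, saturation and well-above-background columns are flags of 0 or 1 per spot. The authors also deposited a table of processed intensity values for 750 of the 956 non-control probes. Per the series' design text, some probes hybridized with a cultured relative, and 206 probes are not in that table. Its method, reference and centring are not given in the sources used here. Its scale is linear: its log2 values correlated at r = 0.992 to 0.996 per array with quantile-normalized spot means. The median of its columns ran from 4.7 to 7.3. The direction of a value (higher is brighter) follows from its rank correlation of 0.994 to 0.999 with the spot means.

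Each probe was printed 15 times. Spots with an outlier flag (238 to 809 of 14340 per array) were dropped, log2 processed signals were averaged per probe, and each array's 75th percentile was subtracted. The percentile was taken over the 31 probes of the value table detected on all 7 arrays, because most probes were not detected on any array. A probe counted as detected where a share above 0.5 of its spots were flagged well above background. No spot was saturated (0 on every array). Signal over background and the number of arrays limit the precision. The lowest detected probe had an intensity of 14.8 to 19.0 on the first slide and of 3.73 to 6.70 on the second.

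Probes in the value table that were detected on at least 3 arrays were tested (170). Their log2 values were fitted in limma 3.58.1 (R 4.3.3) with station and depth (per 10 m) as terms, lmFit and eBayes, and Benjamini-Hochberg adjustment at 0.05. A second fit added the interaction of station and depth. eBayes estimated an infinite prior, so that all probes were given 1 common SD of 0.77 (log2) and the 4 residual degrees of freedom of a single probe did not enter. This assumes that probes vary independently and alike. On simulated data with independent noise for the station comparison (170 probes, 40 of them changed, 50 simulations), 12.0% of changes of 1 log2 unit, 74.4% of changes of 2 and 99.0% of changes of 3 were recovered, and 0.754% of unchanged probes were called. The simulation does not cover noise shared between probes.

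The arrays lie on 2 slides. The first holds the station 2 arrays of 4, 11 and 21 m. The second holds the station 2 array of 30 m and the 3 station 19 arrays. Slide was used as a block, and the comparison was repeated within the second slide, as alternatives.

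The files give each probe a contig name with start and end or the name of an insertion sequence, and no gene symbol or product. All 924 regions with coordinates have lengths that are multiples of 3 (coding length). The files do not pair contig names with genomes or genes, so probes are grouped here by the form of their name: numbered contigs, contigs whose names hold CBZS, contigs whose names hold CAIS, and insertion sequences. One number can occur in more than 1 assembly. No genome was used here. The 22 gene lists and 10 lists for other organisms fixed before the data were examined matched 0 probes. The set tests (limma's camera with its preset correlation of 0.01, and fry) were run instead on the 4 probe sets and on the contigs with at least 4 tested probes, a choice made after the files were seen. Medians of the larger probe sets were compared by exact two-sided permutation over the 35 splits of the arrays, for which the smallest p is 0.0286, and over 144 arrangements of depths within station.

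The rule for naming probes, fixed before the data were examined, took the 10 largest differences past the threshold in each direction, or the smallest p where fewer than 5 passed, and allowed a probe without a gene symbol only among the top 3. The files pair no probe with a gene, so the number was held to 2 in each direction, fewer than this rule allows. The third lower probe, contig 43 at 8021 to 9229, is given only with its bound. Alternatives listed before the data were examined changed the background correction, the scaling, the filter, the probes included, the spot summary, the model and the arrays. Normexp was run on median signals because the files have no mean signal column. A common floor, spike-in scaling (8 of 10 spike-in probes), kept outlier spots, probes detected at both stations, each probe's own variance and a split of contig numbers were added after the data were seen.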

Results

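The array data describe RNA of plankton communities filtered at 2 stations of the western tropical North Atlantic, with probes for the nitrogen-fixing cyanobacteria Richelia intracellularis and Calothrix rhizosoleniae, which form heterocysts and live with diatoms. Station 2 was sampled at 4, 11, 21 and 30 m and station 19 at 2, 21 and 36 m, with 1 array for each depth. Of the 750 probes in the authors' value table, 82, 82, 98 and 190 were detected at station 2 in order of depth, and 254, 136 and 142 at station 19. The 190 and all station 19 counts come from the second slide, where the lowest detected intensity was lower. At 1 common limit of -2.58 on the scaled values, counts of numbered contig probes were 64, 70, 66 and 49 at station 2 and 47, 36 and 39 at station 19. A total of 445 probes were detected on no array and 31 on all 7. The 170 probes tested comprised 129 of numbered contigs, 34 of CBZS contigs, 4 of insertion sequences and 3 of CAIS contigs.

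The first comparison asked which transcripts differed between the stations once depth was allowed for. The numbered contigs with at least 4 tested probes were 9, 20, 43, 50, 54, 55 and 81, and their probes were mostly lower at station 19. Of their 45 tested probes, 38 were lower and 1 was higher, with a median difference of -2.86 on the log2 scale. The median stayed below 0 under every other scaling and with normexp on the median signals (-2.59 to -0.61). All 10 tested probes of contig 43 were lower, with a median of -3.09. With the 7 probes that were dim on every station 19 array at their bounds, the median of the 45 was -2.56. The other 84 tested probes of numbered contigs went both ways, with 14 lower, 16 higher and a median of 0.76. Those 14 also lie on contigs numbered up to 100, since 0 probes of contigs above 100 were lower, so the drop is not particular to the 7 contigs. Of the 34 CBZS contig probes, 4 were higher, 0 lower and 30 did not pass, with a median of 0.79. That median was 0.09 with normexp on the median signals, 1.02 with quantile normalization, 1.06 with scaling over all probes of the value table, 1.88 with the deposited values, 2.41 with spike-in scaling and 0 with a common floor. Of these probes, 24 of 34 were well above background on at most 1 station 2 array, and with the 3 that were dim on all of them at no difference the median was 0.55. Scaling each contig set by itself removes a shift of a whole set and cannot test it. Of the CAIS contig probes, 2 of 3 were lower, and 0 of 4 insertion sequence probes passed.

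Across all 170 probes, limma called 75 between stations, 21 higher and 54 lower at station 19, at a Benjamini-Hochberg adjusted p under 0.05, and 90 at an unadjusted p under 0.05. These calls rest on the common spread that eBayes gave to every probe: with each probe's own variance 0 passed, the lowest adjusted p was 0.0559 and 80 had an unadjusted p under 0.05. At a looser cut than the one used here, an adjusted p under 0.1, 76 passed with their own variance. Spike-in scaling called 40 higher and 2 lower. It shifts all probes of an array alike, leaving the 7 contigs at -3.60 relative to the other probes, and the spike-in means followed the slides (12.6 to 13.3 on the first, 10.4 to 11.0 on the second). The authors' deposited values gave 79 higher and 44 lower. With slide as a block, 38 passed, 4 higher and 34 lower, but the station difference then rests on 1 station 2 array (30 m), the only one on the second slide. Without the 2 m array of station 19 the higher calls numbered 7, and without its 36 m array 10. The arrays of the 2 stations did not overlap for 89 of all 170 probes. Chance gives 5.71% for arrays that could be exchanged, which the slides do not allow, and the probes are not independent (first principal component, 80.9% of the variance). Of the called probes, 63 were detected at both stations, 4 were not well above background on any station 2 array and 8 on any station 19 array.

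**Figure D1:**
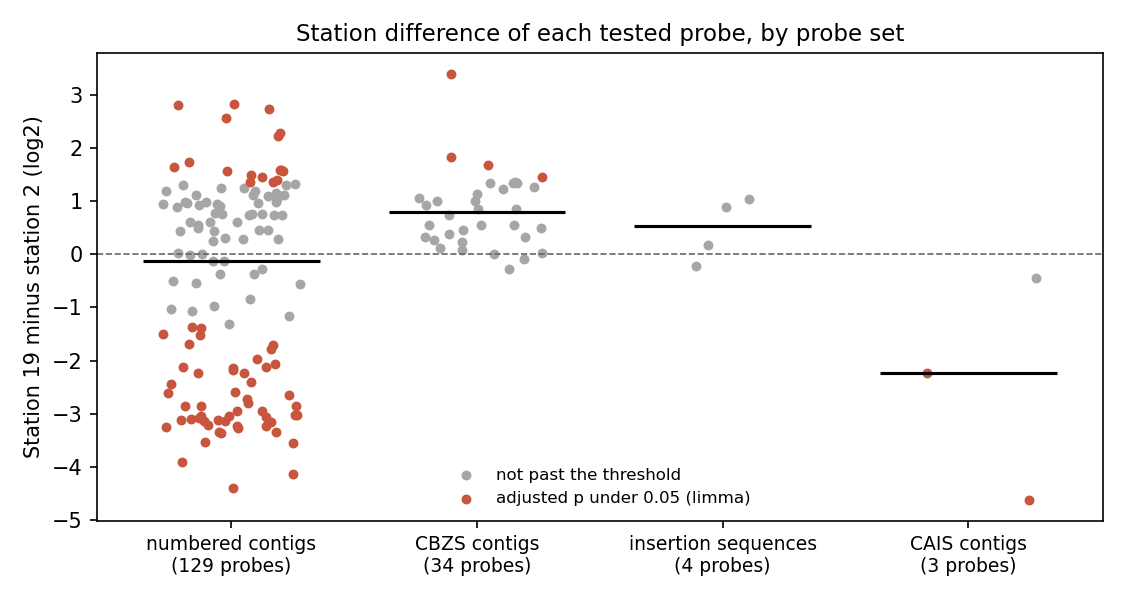
Difference between station 19 and station 2 (log2, vertical axis) of each of the 170 tested probes in 4 probe sets (horizontal axis), with red points for adjusted p under 0.05 in limma, grey points for the others and a line at each median. The numbered contigs spread to both sides with 52 lower and 17 higher calls, while 32 of 34 CBZS probes lie above 0 (34 with quantile normalization, the deposited values or spike-in scaling, 33 with scaling over all probes of the value table, 30 with normexp on the median signals, 14 with a common floor, where most values lie at the floor, and 10 with each contig set centred on itself).

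Named probes are given by contig and position, since the files do not pair them with genes. The highest fitted difference was that of CBZS contig 248 at 86 to 604, with a log2 mean of -4.95 ± 0.56 (SD, n = 4) at station 2 and -1.56 ± 0.60 (SD, n = 3) at station 19. Its fitted difference was 3.38 with an SE of 0.59 (limma, adjusted p = 4.47e-07), and 3.40 within the second slide. Numbered contig 1208 at 7286 to 7687 had a fitted difference of 2.82 (limma, adjusted p = 1.30e-05) and of 2.51 within the second slide. Both probes were well above background on 3 of 3 station 19 arrays but on 1 of 4 station 2 arrays (30 m), so that their station 2 means, and the sizes and order of these differences, are mostly set by values not above background. CAIS contig 666 at 15 to 149 went from 3.75 ± 0.82 (SD, n = 4) at station 2 to -1.02 ± 1.34 (SD, n = 3) at station 19. Its fitted difference, with depth as a term, was -4.61 (limma, adjusted p = 5.10e-12), and -3.67 within the second slide. Numbered contig 43 at 28919 to 29722 had a fitted difference of -4.40 (limma, adjusted p = 3.34e-11) and of -3.71 within the second slide, and was well above background on 4 of 4 station 2 arrays and 2 of 3 station 19 arrays. The 2 higher probes no longer passed with normexp on the median signals, at 0.66 (adjusted p = 0.442) and 0.55 (adjusted p = 0.575). The CAIS contig 666 and contig 43 probes shrank to -3.35 and -1.39 but still passed (limma, adjusted p = 3.08e-15 and 0.00672). The offset used with normexp shrinks differences of dim probes by construction. None of the 4 has an adjusted p under 0.05 with its own variance, as no probe does.

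Tested as sets with camera's preset correlation, 7 of 11 sets passed. The numbered contigs as a whole (adjusted p = 0.00365) and contigs 9 (adjusted p = 0.00365), 43 (adjusted p = 2.97e-06), 50 (adjusted p = 0.0269), 54 (adjusted p = 0.0102) and 81 (adjusted p = 0.0269) were lower relative to the other probes, and the CBZS contigs were higher (adjusted p = 0.000691). For the CBZS contigs, the other probes include those of contigs 9, 20, 43, 50, 54, 55 and 81. The CBZS median was 0.79, against 0.75 for all tested probes outside those contigs, CBZS included. The camera result therefore does not show a rise particular to the CBZS contigs. By fry, which asks whether the probes of a set move one way and does not compare them with other probes, 9 of 11 passed, among them contigs 20 (adjusted p = 0.0128) and 55 (adjusted p = 0.0111) and the CAIS contigs (adjusted p = 0.0128), and the CBZS contigs did not (adjusted p = 0.139). With an estimated correlation 0 of 11 passed, with adjusted p = 0.292 for the numbered contigs and contigs 43 and 54, adjusted p = 0.344 for contigs 9, 50 and 81, and adjusted p = 0.382 for the CBZS contigs. The estimated correlation of contig 43 probes was 0.90 and that of CBZS probes 0.61. These sets were formed after the files were seen. Adjusted over the list alone, 10 of 10 probes of contig 43, 7 of 9 of contig 9 and 2 of 34 of the CBZS contigs passed.

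**Figure D2:**
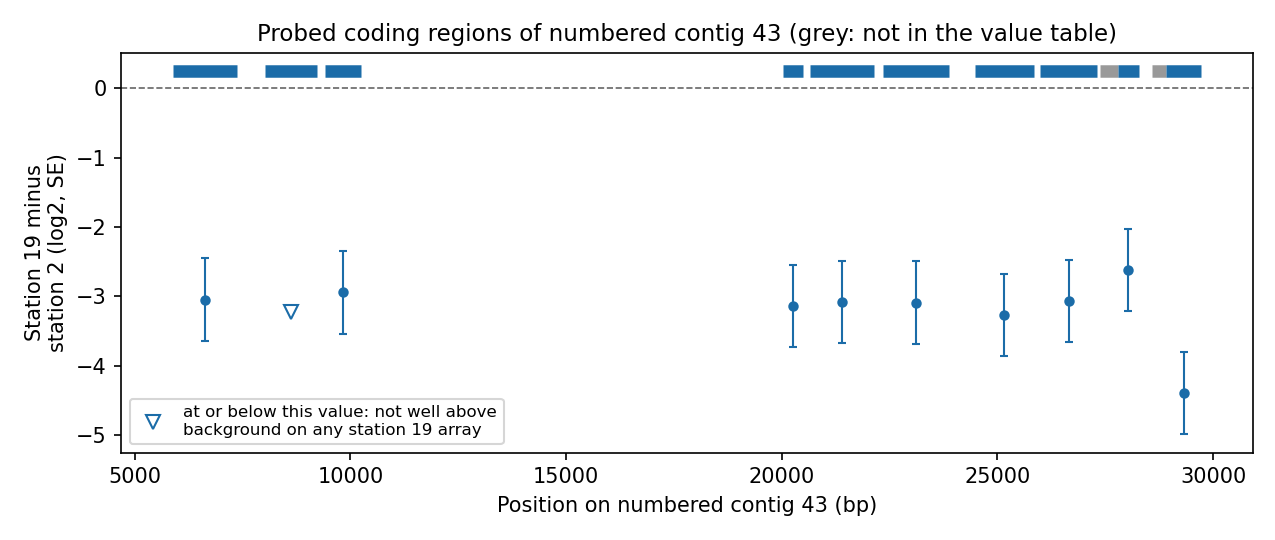
Station difference (log2, vertical axis, bars give the SE) of the probed coding regions of numbered contig 43 against position (bp, horizontal axis), with the extent of each region drawn as a block at the top and regions outside the value table in grey. The region at 8021 to 9229 was not well above background on any station 19 array and is drawn at its bound (open triangle), at least 9.35-fold lower. Of the 9 others, 1 was detected on all 3 station 19 arrays, 6 on 2 and 2 on 1, so most fitted values, which reach from -4.40 to -2.62, rest partly on dim values.

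The series' title speaks of 2 strains, and the signal of the larger probe sets was compared on each array. The median of the 129 numbered contig probes was -2.82 ± 0.31 (SD, n = 4) at station 2 and -3.39 ± 0.34 (SD, n = 3) at station 19 (exact permutation p = 0.114). That of the 34 CBZS probes was -4.12 ± 0.55 (SD, n = 4) and -3.39 ± 0.49 (SD, n = 3) (exact permutation p = 0.171). The CBZS median less the numbered median was higher at station 19 by 1.30 (exact permutation p = 0.0571, adjusted p = 0.257 over 6 tests), and by 0.66 within the second slide. The numbered difference turned to 0.26 with the deposited values and 1.17 with spike-in scaling, and the CBZS difference to -0.65 without a filter on dim probes. None of these differences passed in the setting above, and the smallest p that the 35 splits allow is 0.0286. The numbered set did not move as a whole. In a split chosen after the data were seen, its median moved by -2.22 for contigs numbered up to 100 and by 0.82 above 100. The CBZS median moved by 0.72, so the 1.30 cannot be read as a contrast of 2 strains.

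**Figure D3:**
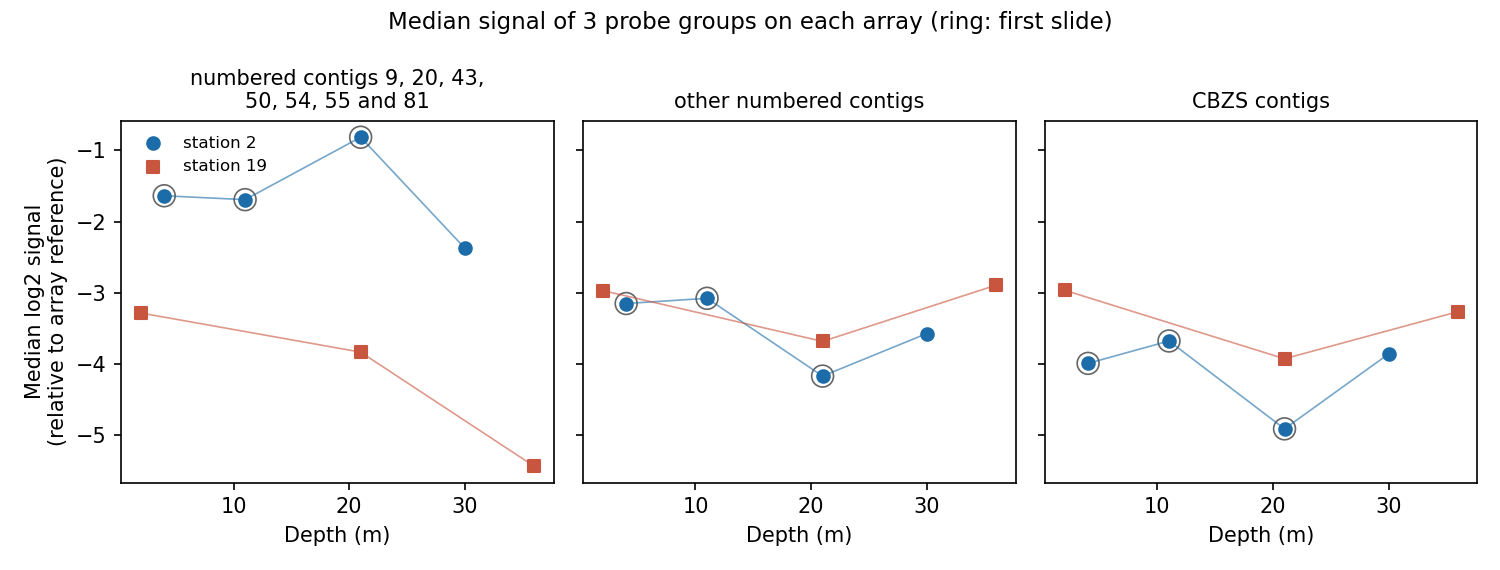
Median log2 signal (vertical axis, relative to each array's reference) of 3 probe groups against depth in metres (horizontal axis), with circles for station 2, squares for station 19 and rings around the arrays of the first slide. The 7 contigs lie between -2.37 and -0.81 at station 2 and between -5.44 and -3.29 at station 19.

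The only depth sampled at both stations was 21 m, with 1 array each and no test. These 2 arrays lie on different slides, so station and slide cannot be told apart there. There, 13 of the 170 probes were at least 4-fold higher at station 19 and 57 at least 4-fold lower, 56 of them on numbered contigs. Of the 13, only 2 were well above background on both arrays, and 3 of the 11 others stayed 4-fold higher with the dim value at its array's lowest detected probe. Of the 57, 34 were well above background on both, and 19 of the 23 others stayed 4-fold lower in this way. The split followed the scaling: with the authors' deposited values 71 were higher and 28 lower.

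The second comparison asked which transcripts changed with depth within the stations. Numbered contig 1405 at 7737 to 8408 rose by 1.04 per 10 m with an SE of 0.25 (limma, adjusted p = 0.00547). Its log2 values were -1.82, -2.05, -2.01 and 2.00 at station 2 and -0.11, 0.04 and 2.86 at station 19, in order of depth, so that the deepest array of each station carried the rise. Its slope was 0.65 (adjusted p = 0.523) without the 30 m array of station 2 and 1.46 without the 2 m array of station 19, and it stayed near its size but no longer passed without the 11 m array of station 2 (1.00, adjusted p = 0.0576) or the 36 m array of station 19 (0.94, adjusted p = 0.129). A probe of the insertion sequence ISMma19 had a fitted slope of 0.88 per 10 m (limma, adjusted p = 0.0367). It was well above background on 1 of 4 station 2 arrays (30 m) and 2 of 3 station 19 arrays (21 and 36 m), so its shallow values are not measured levels and neither is the size of the slope. These were the 2 calls among 170 probes, and 24 had an unadjusted p under 0.05. Neither passed with slide as a block (slopes of 0.65 and 0.78), with quantile normalization (0.97 and 1.14) or with each probe's own variance, which leaves the slopes as they are (0 calls each). Slide as a block gives the same slopes as leaving out the 30 m array of station 2, the only array of its station on its slide. It is therefore not a separate check. The ISMma19 slope was 0.60 (adjusted p = 0.998) without the 2 m array of station 19, and it did not pass either without the 11 m or 30 m array of station 2 or the 36 m array of station 19 (0.90, 0.78 and 0.72). Further, 10 probes passed without the 21 m array of station 2.

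No probe passed in the falling direction with all arrays, whereas 8 of the 10 calls without the 21 m array of station 2 and 31 of the 33 without a filter on dim probes were falling. Dropping the filter brings in 445 probes detected on no array. The median slope of all tested probes was then -0.34, against -0.17 in the main setting, so the 31 cannot be read as separate falls. In the main setting, the smallest unadjusted p values for a falling slope belonged to numbered contig 9 at 77900 to 78667, with a slope of -0.72 per 10 m (limma, adjusted p = 0.153), and numbered contig 20 at 352618 to 353994, with a slope of -0.71 (limma, adjusted p = 0.153). Neither was well above background at 36 m of station 19 (log2 values of -6.15 and -6.34, below that array's lowest detected probe at -4.37), so the sizes of these slopes are not measured, and without that array they were -0.15 and -0.12. Without the 21 m array of station 2 both passed (limma, adjusted p = 0.0183 and 0.0191). The CBZS median had a slope of -0.11 (exact permutation p = 0.549) and the numbered median a slope of -0.16 (exact permutation p = 0.132). None of the 11 probe sets passed with depth by camera (0), with an estimated correlation (0) or by fry (0).

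The slopes of the 2 stations were compared by the interaction term. With limma 0 of 170 probes passed, and 4 had an unadjusted p under 0.05. With normexp on the median signals, which changes the background correction and the signal it starts from and adds an offset, 92 passed, 91 of them positive. The median interaction effect of all tested probes moved from 0.023 to 0.54 with it. This count therefore cannot be read as 92 separate differences in slope.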

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

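All tests of explanations in this part were chosen after the results were seen. Chance flags about 1 in 20 groups of 4 arrays as holding an outlier. Of 27 such groups at station 2, 6 held one by Dixon's ratio.

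The station 2 array of 30 m stood apart with 190 detected probes, against at most 98 on the other 3, with 36 detected CBZS probes against at most 9, and with 5 CAIS probes against 3. The probe of contig 1405 stood apart on the same array at 2.00, against at most -1.82 on the others. The probe of contig 1208 was at -5.76 on the 21 m array of station 2, against -4.53 for the nearest other. The median of contig 43 was at 0.27 on that array, against -0.76 for the nearest. Among data that the comparisons do not use, the probes left out of the value table gave a signal: on the array with the fewest, 32.5% of them were detected, against at most 2.60% of negative control spots on any array.

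The first pattern weighed is the lower signal of numbered contigs 9, 20, 43, 50, 54, 55 and 81 at station 19. In the main setting 1 of the 35 splits of the arrays gave as many as 75 calls, the stations themselves. The highest other split gave 53. These calls are counted over all 170 tested probes in both directions (21 higher, 54 lower) and become 0 with each probe's own variance. The count therefore does not test these contigs by themselves. The splits also ignore the slides, so they cannot decide whether chance gave this pattern. Kept within the slides there are 4 splits, too few for a share under 0.05, and the highest other of these gave 0. The different lower limits of the slides are argued against as the whole cause: among 31 probes detected on all arrays, the median of 10 probes of these contigs less that of the 21 others still differed by -2.01 (exact permutation p = 0.0286, the smallest possible). A difference between slides cannot be told apart, because within the second slide the value of -2.27 rests on 1 station 2 array. On that array (30 m) the median of these contigs less that of the other tested probes was 1.29. It was 1.55 to 3.43 on the first slide and -2.46 to -0.16 at station 19. Among the probes detected on all arrays, the value within the second slide was smaller, at -1.19, and rests on the same array. A difference in community or strain between the stations stays open as untested.

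The second pattern is the rise of the contig 1405 probe with depth. At station 19, where all arrays share a slide, the 36 m array lay 2.89 above the mean of the 2 others, which a difference between slides cannot give. At station 2 the 30 m array lay 3.96 above the mean of the first slide, and there slide and depth cannot be told apart, because that array alone lies on the second slide. Stray spots are argued against, since the slope over the median of spots was 1.05. A response to depth stays open, and rests on 1 array per station.

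The third pattern is the larger number of detected CBZS probes at station 19 (68, 28 and 45, against 9, 9, 5 and 36). At a common limit of -2.58 on the scaled values, the counts were 6, 9, 4 and 6 at station 2 and 13, 8 and 15 at station 19, so that the lowest at station 19 lay below the highest at station 2 (difference -1). This is consistent with the lower detection limit of the second slide as a source of much of the difference in detection. At the common limit the numbered contig counts were 64, 70, 66 and 49 at station 2 and 47, 36 and 39 at station 19. All station 19 counts of that set thus lay below those of station 2, so the 2 sets did not move alike. A difference in the amount of CBZS transcript stays open.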

How the results depend on the processing

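Alternatives were chosen before the data were examined, except the common floor, spike-in scaling, own variance, kept outlier spots, probes detected at both stations and the split of contig numbers, which were added afterwards. Signal over background limits most probes, and where no cause is given below the cause was not tested.

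Between stations, the main 75 calls (21 higher, 54 lower at station 19) became 11 with normexp on the median signals (1 higher, 10 lower), 117 with quantile normalization (65 higher, 52 lower), 123 with the authors' deposited values (79 higher, 44 lower), 42 with spike-in scaling (40 higher, 2 lower), 189 of 286 over all non-control probes (113 higher) and 17 of 31 over probes detected on all 7 arrays (7 higher, 10 lower, with fewer tested). The higher calls numbered 56 when scaled over all probes of the value table and 54 when scaled within each contig set, and the lower calls 47 and 43, so that the lower share went from 72.0% to 45.6% and 44.3% mainly because more were higher. Quantile normalization gave 44.4%, the deposited values 35.8%, all non-control probes 40.2% and spike-in scaling 4.76%. These scalings moved the median difference of all tested probes from 0.30 by 0.36 (quantile), 0.27 (all probes of the value table), -0.32 (within contig sets), 1.02 (deposited values) and 1.62 (spike-in), and normexp by -0.26. The 7 contigs stayed below the other probes in all of these, with a difference of -0.71 for normexp, whose offset shrinks dim values, and of -3.87 to -2.88 otherwise. Spike-in scaling and scaling over all probes of the value table subtract 1 value per array. They leave this difference at its main -3.60 and cannot test it.

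Slide as a block left 38 (4 higher, 34 lower), and 20 without depth (3 higher, 17 lower). Within the second slide 0 passed (0 higher, 0 lower, 37 at an unadjusted p under 0.05 in limma). In these fits the station difference rests on 1 station 2 array. Each probe's own variance gave 0 (0 higher, 0 lower), with 80 unadjusted and 76 at an adjusted p under 0.1. A common floor gave 0 calls (0 higher, 0 lower, 38 unadjusted), because 48 probes then had no spread at all and the prior was estimated from them. The same floor without those 48 probes, run after that 0 was seen, gave 31 of 122 (10 higher, 21 lower). The median difference of contig 43 went from -3.09 (median SE 0.59) to -2.01 (median SE 0.46) under the floor, while the median of the 7 contigs went from -2.86 to -0.89 and their difference from the other probes from -3.60 to -0.89. Without single arrays the count ran from 58 (without the 2 m array of station 19) to 79, with 7 to 29 higher and 50 to 53 lower. The higher calls numbered 7 without that array and 10 without the 36 m array of station 19.

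With depth, the 2 calls became 1 with normexp, with scaling within contig sets, with the deposited values and over probes detected on all arrays. The ISMma19 probe was not among those tested with scaling within contig sets or over probes detected on all arrays, so it could not pass there. The calls became 0 with quantile normalization, scaling over all probes, all non-control probes, spike-in scaling, either form of the common floor, slide as a block, station 19 alone, station 2 alone, log2 depth and own variance. For depth, slide as a block is the same check as leaving out the 30 m array of station 2. Without a filter there were 33 (2 rising, 31 falling, with the median slope of all tested probes moved by -0.17), and without single arrays 0 to 10, the 10 (2 rising, 8 falling) without the 21 m array of station 2 and 0 without the 11 m or 30 m array of station 2 or the 36 m array of station 19. The slope of the ISMma19 probe was -0.11 with normexp. The interaction gave 92 with normexp (91 positive, with the median of all tested probes moved by 0.52), 2 without a filter and 0 to 1 without single arrays.

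The numbered contig median between stations (-0.57) was 0.26 with the deposited values, 1.17 with spike-in scaling, -0.29 (exact p = 0.0286) with quantile normalization, -0.83 (exact p = 0.0286) over probes detected on all arrays, -0.19 within the second slide, -2.22 (exact p = 0.0286) for contigs numbered up to 100 and 0.82 above 100, and -0.74 to -0.40 without single arrays. It nearly vanished over all probes (-0.0029) and with the common floor (-0.022). With normexp it was -0.17 (exact p = 0.714), with scaling over all probes of the value table -0.19 (exact p = 0.543), and without a filter -0.73 (exact p = 0.229). The CBZS median (0.72) was -0.65 without a filter, 1.94 (exact p = 0.0286) over all probes, 0.0037 with normexp, 0 with the common floor, where most CBZS values lie at the floor, and 0.46 to 1.00 without single arrays. CBZS less numbered (1.30) was 1.67 with the deposited values, 1.99 over probes detected on all arrays and 1.94 over all probes (each exact p = 0.0286), 0.18 with normexp, 0.072 without a filter (exact p = 0.486), 0.022 with the common floor (exact p = 1), 0.66 within the second slide and 1.07 to 1.51 without single arrays. With depth, no main slope passed. The numbered slope turned to 0.19 (all probes of the value table), 0.027 (deposited values) and 0.24 (spike-in), and ran from -0.28 to -0.12 without single arrays. The CBZS slope turned to 0.11 (quantile), 0.25 (all probes of the value table), 0.16 (deposited values) and 0.29 (spike-in), and ran from -0.23 to 0.017. CBZS less numbered turned to -0.020 (normexp) and -0.049 (detected on all arrays), and ran from -0.085 to 0.15.

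The 7 contig and probe sets past the threshold between stations became 0 with an estimated correlation, 4 with normexp, 2 with scaling within contig sets and 4 with slide as a block, with 5 to 7 without single arrays. With depth the 0 sets became 1 with normexp, 1 with quantile normalization and 3 with scaling within contig sets, and 0 to 1 without single arrays. At 21 m the 13 probes at least 4-fold higher became 0 (normexp), 39 (quantile), 30 (within contig sets) and 71 (deposited values), and the 57 lower became 7, 30 and 28 with normexp, quantile normalization and the deposited values. The probes of CBZS contig 248 and contig 1208 kept their direction in all 20 alternatives, as did CAIS contig 666 in 21 and contig 43 at 28919 to 29722 in 20. Their sizes were not kept in all of them. With the common floor, where 0 probes passed, the first 2 shrank to 0.97 and 0.68. The contig 43 probe shrank there to -2.57, and that of CAIS contig 666 stayed at -4.61.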

Other observations

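The tests in this part were chosen after the data were seen. The 206 probes outside the value table, which the design text ties to cross-hybridization, were not part of the comparisons. Of the 78 CAIS contig probes among them, 40 were detected on at least 3 arrays, and 37 of these had a negative station difference. Their median per array was -1.63 ± 0.43 (SD, n = 4) at station 2 and -3.78 ± 0.92 (SD, n = 3) at station 19, a difference of -2.15 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0429 over 3 sets) and of -1.57 within the second slide. The 53 left-out numbered contig probes went the same way, with 47 negative, by -1.94 (exact permutation p = 0.0286, adjusted p = 0.0429), so the drop is not particular to CAIS contigs. The 23 left-out CBZS probes went the other way by 0.63 (exact permutation p = 0.171, adjusted p = 0.171). As these probes can bind transcripts of a relative, the values cannot be assigned to 1 organism.

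A hypothesis is that the numbered contigs hold more than 1 population of probes, which move apart between stations. Of the 75 tested probes of contigs numbered up to 100, 52 were lower at station 19 and 4 higher (median -2.23). Of the 54 above 100, 0 were lower and 13 higher (median 0.96). The difference of the medians per array was -3.04 (exact permutation p = 0.0286) and -1.78 (exact permutation p = 0.0286) without the 45 probes of contigs 9, 20, 43, 50, 54, 55 and 81, which make up most of the first group. The split at 100 was chosen from these values. With normexp the difference was -0.55 (exact permutation p = 0.0571) and with a common floor -0.60 (exact permutation p = 0.114). Contigs up to 100 held 81 of the 93 left-out numbered probes (81 of 243 on the array, against 12 of 313 above 100, Fisher's exact test p = 3.59e-21). This test takes probes of 1 contig as independent, so its p may be too small. Among left-out probes the difference was -2.52 (one-sided permutation p = 0.00948), but only 3 of them lay above 100 and the permutation takes probes of 1 contig as independent, so this does not decide. Whether probes of 1 contig share their difference is not decided. The SD within contigs was 1.13, against a median of 1.88 for 10000 shuffles of contig names over 82 probes (one-sided permutation p = 1e-04, the smallest they can give). The shuffles mixed contigs up to 100 with those above 100, so the gap between these 2 groups alone can lower that SD.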
